A study of Mus musculus with 14 samples.

How the data were processed

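MicroRNA was measured in 14 samples of total RNA from adherent peritoneal macrophages of BALB/c mice, each hybridised to 1 array. Per the labels' protocols, cells were harvested 3 days after thioglycollate injection or 21 days after implantation of the nematode Brugia malayi. They were kept for their adherence to plastic and were more than 80% pure by F4/80 and CD11b staining. RNA was labelled with the dye Hy3 and hybridised to miRCURY LNA arrays, so each array has 1 colour. Samples were grouped by the elicitation and genotype named in their labels: thioglycollate wild type (3 arrays), thioglycollate IL-4R KO (3 arrays), nematode wild type (4 arrays) and nematode IL-4R KO (4 arrays), where IL-4R KO stands for IL-4 receptor knockout. The labels do not say that replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

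The deposited slide files hold, per the file headers, the foreground intensity and the local background intensity of each spot on a linear scale, quantified with fixed circles and neither background subtracted nor normalized by the authors. The scanner software is not given in the sources used here. Each of the 7 slides holds 2 arrays. Every slide holds 1 group except slide 12, which holds thioglycollate wild type replicate 3 and thioglycollate IL-4R KO replicate 1. The slides were scanned group after group, per the file headers, so scan order runs with the groups. The authors' deposited value table is on the linear intensity scale and uncentred. All of its values equalled foreground minus background of the matching spots within 0.001, and its column medians ran from 10.5 to 19.1.

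An array carries 343 probes named for mouse miRNAs, each in 3 spots, and 966 named for miRNAs of other species, in 2901 spots, with 702 blank and 24 negative control spots among the rest. Values were read and analysed in R 4.3.3 with limma 3.58.1. Background was corrected by normexp with an offset of 50 over all spots of an array. Values were then taken to log2, the spots of a probe were averaged, and arrays were quantile normalized over all named miRNA probes. The offset and the quantile step compress fold changes of dim probes. The brightest probes are also limited: where miR-21 takes the top rank on every array of both groups its log2 fold change is 0 by construction, and miR-720 shares tied ranks. No mouse spot was saturated.

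The planned detection rule asked for at least 50% of a probe's spots above local background plus 2 SD on at least 3 arrays. It passed all 343 mouse probes, and also between 71.2% and 82.6% of the blank and negative control spots of an array, so it removed nothing. A stricter filter was chosen after seeing this: a probe above the 95th percentile of net signal of the blank and negative control spots of its array on at least 3 arrays, which 208 mouse probes passed. The 12 spots of an unlabelled kind were taken out of the blanks after the data were seen; with them among the blanks, 195 mouse probes passed. This percentile also marks, for each named miRNA, the arrays on which it stood above blank spots. A miRNA below it on every array of 1 group has only a bound there. Its fold is given as "at least": the mean of the bright group against the dim group's mean of the higher of the lowest signal above blanks and the probe's own value per array. That bound is an estimate from means and carries no sampling error.

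Each comparison was fitted with limma (lmFit with 1 mean per group over all 14 arrays, then eBayes), with a two-sided moderated test, Benjamini-Hochberg adjustment within the comparison and a threshold of 0.05 on the adjusted p. The comparisons were nematode against thioglycollate in each genotype, wild type against IL-4R KO in each elicitation, and the interaction of both factors. Lists of miRNAs were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation, and with fry, for lists of at least 3 measured members. Groups, tests, lists, the rule for named miRNAs and most alternatives were fixed before the data were examined. The rule names, per comparison, up to 10 miRNAs with the largest and 10 with the smallest log2 fold change among those past the threshold whose 2 groups do not overlap (6 and 6 for the thioglycollate genotype comparison and the interaction, the latter without the condition on overlap). It adds miR-378 and its star arm, miR-155, miR-146a, miR-223, miR-21, miR-142-3p, miR-511, miR-125b-5p, miR-199b, miR-342-3p and miR-150, and the members that changed most in each list past the threshold.

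The 20 lists were IL-4R-linked miRNAs named by the study (miR-378 and its star arm), inflammatory, myeloid and macrophage, miR-17-92 and paralog clusters, let-7, miR-15/16, miR-29, miR-30, miR-26 and miR-101, miR-99 with miR-100 and miR-125b, miR-34 and p53-linked, hypoxia, lymphocyte, neutrophil and granulocyte, erythroid, endothelial, stromal with fibroblast and mesothelial, epithelial, muscle and liver, and the Dlk1-Dio3 cluster. The probes carry old names. The array's miR-422b is the miRNA later called miR-378, and the array's miR-378 is its star arm. Likewise miR-146 stands for miR-146a, miR-342 for miR-342-3p and miR-125b for miR-125b-5p. This table of older names was made from names alone after the files were seen, and it extends the matching rule. No probe was named for mouse miR-511 or let-7a. Probe sequences were not used here, so cross-hybridisation within a family was not assessed.

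The alternatives were no background correction, plain subtraction with values under 50 set to 50, median scaling, cyclic loess, no normalization, the median of a probe's spots, other filters, the authors' value table plus 50, slide as a random block, the replicate number as a factor, the position on the slide as a factor, a fit on only the groups compared, eBayes with trend and robust, and leaving out each array in turn. Added after seeing the data were the filter on blank spots, a normexp offset of 20, the list tests without nematode wild type replicate 4, and the overlap in fits on only the groups compared. Since camera takes no random block, that list test used limma's cameraPR on the statistics of the blocked fit. No 2 arrays held the same values; the highest correlation of log2 net signal between arrays was 0.921.

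The procedure was tested on simulated data in which 60 of 343 probes were changed on top of the measured signals and spread. The changed probes were drawn anew for each contrast, with 1 simulation each, so the counts cannot be compared between contrasts. Of 20 probes changed by a log2 of 2, the threshold was passed by 12 in nematode against thioglycollate in wild type, 4 in the same contrast in IL-4R KO, 10 in the nematode genotype contrast and 7 in the thioglycollate genotype contrast. All were in the right direction. Of 20 probes changed by a log2 of 1, it was passed by 1, 2, 5 and 1. Of the 283 unchanged probes 0, 1, 0 and 0 were called. The median estimate for a simulated log2 of 2 was 0.83, 0.54, 0.59 and 0.59, so changes of these sizes would often be missed and would be understated. Some of the changed probes had a net signal above 32 intensity units. Of these, 2 of 5, 1 of 9, 6 of 6 and 1 of 4 passed at a log2 of 2. Their median estimates were 1.03, 1.01, 1.32 and 0.70. That cut lies below the normexp offset and below the blank percentile of several arrays, and it leaves few probes. It therefore cannot tell whether the limit is one of dim probes alone.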

Results

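The arrays measured miRNAs in peritoneal macrophages of wild-type BALB/c mice and of mice without the IL-4 receptor, through which IL-4 and IL-13 induce alternative activation. Cells were drawn into the peritoneum by thioglycollate, a sterile irritant, or by an implant of Brugia malayi, a filarial worm whose implantation gives alternatively activated macrophages. The elicitations also differ in time, 3 days against 21 days. The arrays hold no probe for the receptor's mRNA, so the knockout itself could not be checked. The median net signal of mouse probes was 14.2 to 31.8 intensity units per array, against 6.69 to 9.18 for blank and negative control spots. Between 33 and 267 of the 343 mouse probes stood above the 95th percentile of blank spots on an array. That percentile itself ran from 12.6 to 111 intensity units per array. Counts of probes or arrays above blank spots therefore also depend on the spread of an array's blank spots, and are not measures of level. The lowest number belonged to nematode wild type replicate 4, whose correlation with the rest of its group was 0.867, against 0.939 to 0.976 for the other 13 arrays. The number of arrays per group limits the precision of every value.

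**Figure D1:**
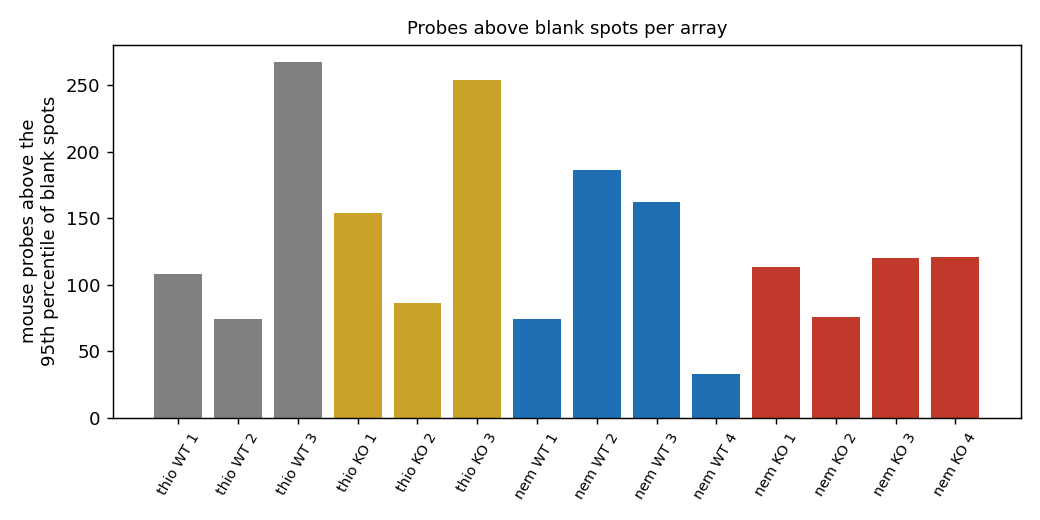
Number of mouse miRNA probes above the 95th percentile of blank and negative control spots on each of the 14 arrays, coloured by group (thio, thioglycollate; nem, nematode; WT, wild type; KO, IL-4R KO). The bars run from 33 in nematode wild type replicate 4 to 267 in thioglycollate wild type replicate 3. The percentile was 111 intensity units on the former array and 12.6 on the latter.

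In wild-type mice, 1 miRNA was higher and 2 were lower in nematode-elicited than in thioglycollate-elicited macrophages. miR-422b, the array's name for the miRNA now called miR-378, whose precursor lies in an intron of the coactivator gene Ppargc1b, was 3.59-fold higher. Its log2 intensity was 9.11 ± 0.53 (SD, n = 4) in nematode-elicited and 7.27 ± 0.18 (SD, n = 3) in thioglycollate-elicited cells (log2 fold change 1.84, SE 0.24, limma adjusted p = 0.00127). miR-146, induced by NF-kB and a brake on Toll-like receptor signalling, was 1.69-fold lower (log2 fold change -0.76, SE 0.12, limma adjusted p = 0.00504). miR-342 was 1.75-fold lower (log2 fold change -0.81, SE 0.16, limma adjusted p = 0.0297). Both stood above blank spots on 2 of 4 nematode and 3 of 3 thioglycollate arrays. The blank percentile was 14.8 to 111 intensity units on the former and 12.6 to 36.9 on the latter. For all 3 miRNAs, the log2 intensities of the 4 nematode arrays did not overlap those of the 3 thioglycollate arrays.

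The inflammatory list was lower as a group in this comparison (limma camera, adjusted p = 0.0136; adjusted p = 0.134 with an estimated correlation). Of its 9 measured members, 1 fell, miR-146, and 7 had a negative log2 fold change, with a list median of -0.18. Adjusted over the list alone, 3 were lower. The others were miR-221 (log2 fold change -1.21, SE 0.30) and miR-222 (-0.89, SE 0.22), which come from 1 cluster and whose adjusted p over all probes was 0.0696 and 0.0732. Both did pass with no background correction, with the median of spots and among probes above blank spots. miR-222 also passed with median scaling, with the replicate number as a factor and without nematode wild type replicate 4. miR-155, a classical product of inflammatory activation, gave 0.11 (SE 0.25, limma adjusted p = 0.938). The miR-17-92 and paralog clusters, linked to proliferation, were also lower as a group (camera adjusted p = 0.0273; adjusted p = 0.506 with an estimated correlation). None of their 13 probes passed the limma threshold over all probes, where 37 of 343 had an unadjusted p under 0.05. Their largest values were -0.83 for miR-18 (adjusted p = 0.0509), -0.76 for 1 of 2 miR-20a probes (0.0649), -0.51 for miR-17-5p and -0.85 for miR-92, which turned to 0.03 with the median of spots. Adjusted over the list alone, 2 of them were lower. The miR-17-92 shift was not past the threshold without nematode wild type replicate 4 (adjusted p = 0.146), with median scaling (0.343) or among probes above blank spots (0.127).

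The myeloid and macrophage list had a median of -0.46 over 10 members, with 0 past the threshold. Its camera adjusted p was 0.112, and fry, which asks only whether the members move one way, gave an adjusted p of 0.00891. Among its members, miR-223, which granulocytes and monocytes express, gave 0.36 (SE 0.20), and miR-142-3p, of haematopoietic cells, -0.66 (SE 0.50), neither past the threshold. The other 14 lists tested had camera adjusted p values from 0.329 to 0.997, including the lymphocyte list, where miR-342 was the 1 of 7 that fell. By fry's mixed test, which allows members to move in either direction, the inflammatory list (adjusted p = 0.00729) and the stromal list (0.0154) passed. The stromal list had no member past the threshold, and its member miR-199b gave 0.67 (SE 0.21, limma adjusted p = 0.232). miR-125b (0.33, SE 0.15), miR-150 (0.17, SE 0.14), miR-21 (-0.43, SE 0.19) and the star arm of miR-378 (0.21, SE 0.12) did not pass. The hypoxia miRNA miR-210 gave 0.10 (SE 0.20), and the endothelial miR-126-3p and miR-126-5p -0.17 (SE 0.10) and 0.07 (SE 0.11).

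Of the 343 probes, 37 had an unadjusted p under 0.05, where 17.2 would by chance, and 27 had groups that did not overlap, where chance gives 5.71% of probes. A fit on only the 7 arrays compared called 0 (23 at an unadjusted p under 0.05), and there miR-422b had an adjusted p of 0.133. The miR-342 call ended in 7 of 16 other settings (2 of which, the planned filters, removed no probe) and without any 1 of 8 single arrays, and the miR-146 call ended in 4 of 16. Without nematode wild type replicate 4, the call count rose from 3 to 9, 6 higher and 3 lower, and included miR-199b, miR-99a, miR-100, miR-194 and miR-365 as higher.

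**Figure D2:**
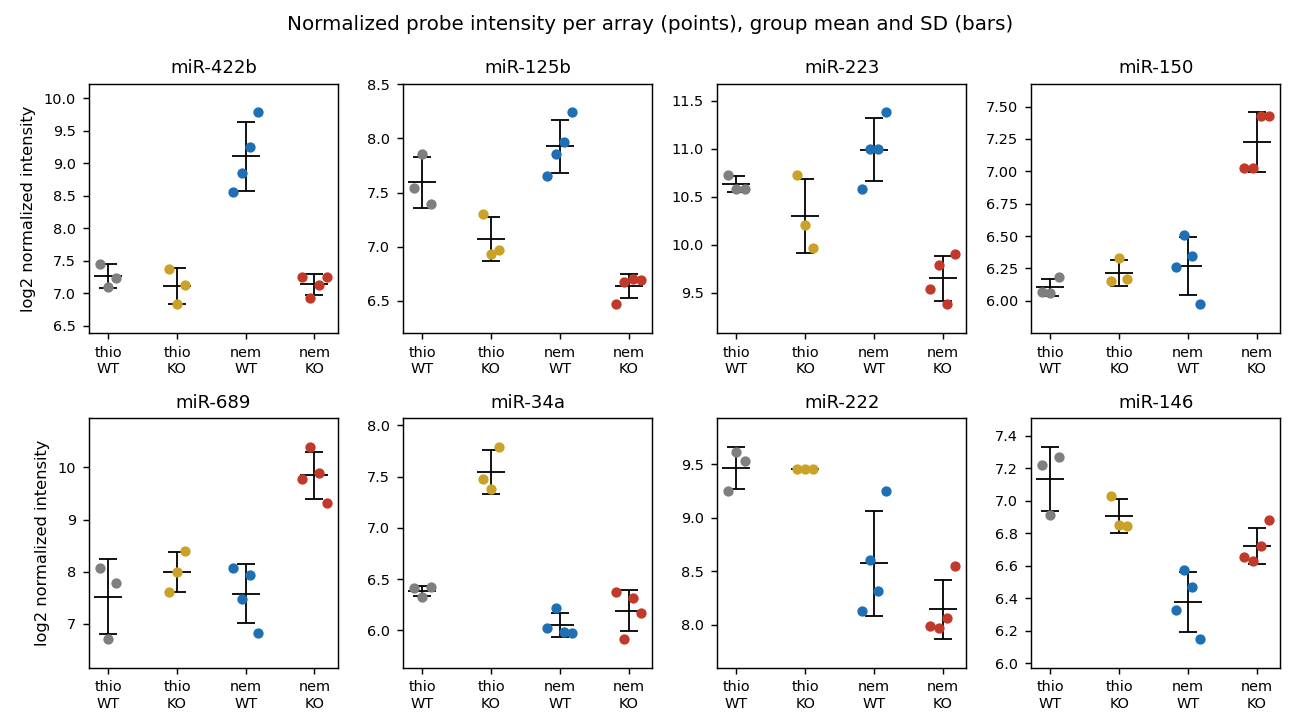
Normalized log2 probe intensity of 8 miRNAs on each array (points) by group, with the group mean and SD (bars; n = 3 for thioglycollate and 4 for nematode groups; each panel has its own axis). The 4 nematode wild type arrays of miR-422b, with a mean of 9.11, lie above those of the other 3 groups, whose means are 7.27, 7.11 and 7.14.

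In mice without the IL-4 receptor, 3 miRNAs were higher and 2 were lower after nematode than after thioglycollate elicitation. miR-34a, a transcriptional target of p53, was at least 2.29-fold lower after nematode elicitation (limma adjusted p = 2.86e-05). Its log2 intensity was 7.55 ± 0.21 (SD, n = 3) on thioglycollate arrays and 6.19 ± 0.20 (SD, n = 4) on nematode arrays, on none of which it stood above blank spots. miR-222 was 2.48-fold lower (log2 fold change -1.31, SE 0.22, adjusted p = 0.00764). miR-150, abundant in mature lymphocytes, was 2.01-fold higher (log2 fold change 1.01, SE 0.14, adjusted p = 0.00107), and stood above blank spots on 4 of 4 nematode and 1 of 3 thioglycollate arrays. miR-689 was 3.60-fold higher (log2 fold change 1.85, SE 0.37, adjusted p = 0.0231). miR-551b passed the test as higher (adjusted p = 0.0422) but stood below the blank percentile on all 7 arrays, so no fold is given.

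miR-422b did not differ detectably in these mice (log2 fold change 0.03, 95% confidence interval -0.49 to 0.54, limma adjusted p = 0.977). The inflammatory list had a median of -0.19 over 9 members, of which 1 fell, miR-222. Adjusted over the list alone, miR-222 and miR-221 (-1.08, SE 0.30, adjusted p over all probes 0.135) were lower. No list passed with camera, where 33 of 343 probes had an unadjusted p under 0.05 in limma. The inflammatory list had an adjusted p of 0.294 and the myeloid list one of 0.0786. fry gave 0.00438 for the myeloid list, with 9 of 10 members negative and 0 past the threshold, and 0.00622 for the miR-34 family, where 1 of 6 fell. fry's mixed test gave adjusted p values of 0.000547 for the miR-34 family, 0.000987 for the lymphocyte list and 0.0125 for the inflammatory list. In the lymphocyte list 1 of 7 rose, miR-150, and the list median was -0.07. Values that did not pass were 0.49 for miR-155 (SE 0.25), -0.65 for miR-223 (SE 0.20), -0.43 for miR-125b (SE 0.15), -0.41 for miR-342 (SE 0.16), -0.38 for miR-21 (SE 0.19), -0.29 for miR-199b (SE 0.21), -0.19 for miR-146 (SE 0.12), -0.11 for the star arm of miR-378 (SE 0.12) and 0.01 for miR-142-3p (SE 0.50), whose sign turned under 4 settings. miR-223 did pass with median scaling and with no normalization, and miR-155 in the fit on only the groups compared.

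Groups did not overlap for 54 of 343 probes, where chance gives 5.71%. The miR-551b call ended in 7 of 15 settings and without any 1 of 11 single arrays, and the miR-689 call ended with plain subtraction and without any 1 of thioglycollate IL-4R KO replicates 1 and 2 and nematode IL-4R KO replicates 1, 2 and 3 (adjusted p = 0.177 with plain subtraction and up to 0.146 with an array left out). The count of 5 was 3 without thioglycollate IL-4R KO replicate 1 or nematode IL-4R KO replicate 2, 8 without nematode wild type replicate 4 or with no normalization, 10 with cyclic loess and 11 in the fit on only these groups.

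Across the 343 probes, the elicitation log2 fold changes of the 2 genotypes had a Pearson r of 0.295 and a Spearman rho of 0.265. Among the 208 probes above blank spots they were 0.295 and 0.298. These comparisons share no arrays, and probes are not independent replicates.

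**Figure D3:**
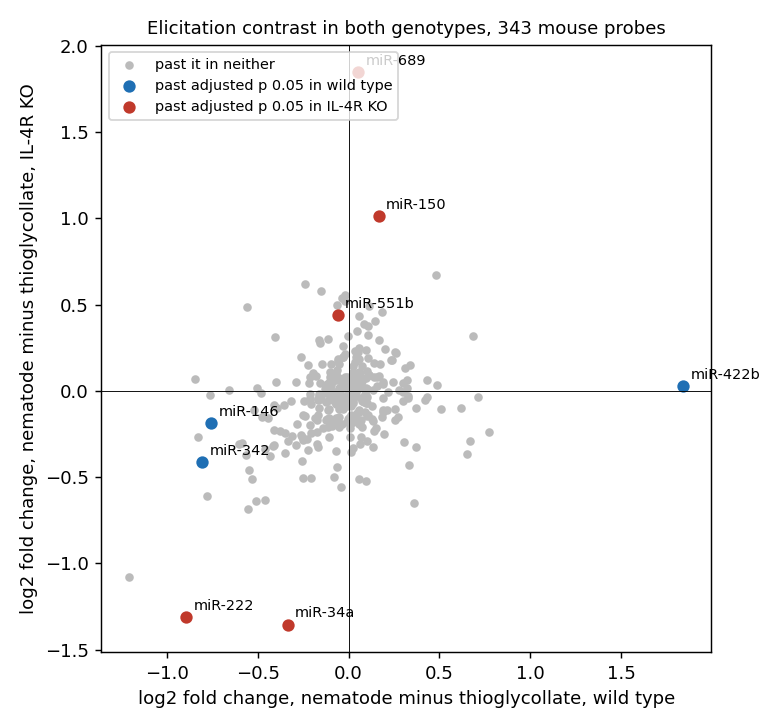
Log2 fold change, nematode minus thioglycollate, in wild type (horizontal) and in IL-4R KO (vertical) for each of the 343 mouse probes, with probes past the limma threshold coloured by genotype and named. miR-422b lies at 1.84 in wild type and 0.03 in IL-4R KO, while the point of miR-34a is its fitted value, for which only a bound, estimated at 2.29-fold without sampling error, is given in IL-4R KO.

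Within nematode-elicited cells, 4 miRNAs were higher and 2 were lower in wild type than in IL-4R KO, the comparison that bears on the receptor in alternatively activated macrophages. miR-422b was 3.91-fold higher in wild type (log2 fold change 1.97, SE 0.22, limma adjusted p = 0.000136), at 9.11 ± 0.53 against 7.14 ± 0.16 (SD, n = 4 each). miR-125b, of the clusters that hold miR-99 and miR-100, was 2.45-fold higher (log2 fold change 1.29, SE 0.14, adjusted p = 0.000136). miR-223 was 2.53-fold higher (log2 fold change 1.34, SE 0.19, adjusted p = 0.000697). Lower in wild type were miR-150, by 1.94-fold (log2 fold change -0.96, SE 0.13, adjusted p = 0.000573), and miR-689, by 4.82-fold (log2 fold change -2.27, SE 0.34, adjusted p = 0.00132). miR-720, a name now given to a fragment of a tRNA, was 2.22-fold higher (log2 fold change 1.15, SE 0.23, adjusted p = 0.0151). In each, the 4 wild type arrays lay on 1 side of the 4 IL-4R KO arrays. miR-150 stood above blank spots on 2 of 4 wild type and 4 of 4 IL-4R KO arrays, and miR-689 on 3 and 4.

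In the list of miR-99, miR-100 and miR-125b clusters, 1 of 5 members rose over all probes, miR-125b. Adjusted over the list alone, 3 were higher and 2 lower. miR-99a (0.68, SE 0.18) and miR-100 (0.56, SE 0.14), whose adjusted p over all probes was 0.0588 and 0.0566, were positive with miR-125b. miR-125a and miR-99b, which share another cluster, were negative (-0.64 and -0.27). The list's camera adjusted p was 0.272 and its fry adjusted p 0.0405. In the myeloid list, 1 of 10 rose, miR-223, and miR-22 gave 0.92 (adjusted p = 0.0566), while the list median was -0.07 (camera adjusted p = 0.967). In the lymphocyte list 1 of 7 fell, miR-150, with a list median of -0.13. The stromal list had a median of 0.05 over 14 members, with miR-199b at 0.80 (SE 0.20, adjusted p = 0.0569). miR-199b did pass with cyclic loess, the median of spots, trend and robust, and an offset of 20. It also passed among probes above blank spots and without nematode wild type replicate 3 or 4. The granulocyte list had 1 of 5 higher, miR-223, and a median of 0.01. The camera adjusted p values of the lymphocyte, stromal and granulocyte lists were 0.272, 0.272 and 0.285. fry's mixed test gave them adjusted p values of 0.0135, 0.0764 and 0.0306. It gave 0.00267 for the myeloid list and for the list of miR-99, miR-100 and miR-125b clusters.

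The miR-17-92 and paralog clusters were lower in wild type as a group (camera adjusted p = 0.0337; adjusted p = 0.652 with an estimated correlation), with a median of -0.16 and 11 of 13 probes negative. None of the 13 passed the limma threshold over all probes, where 43 of 343 had an unadjusted p under 0.05. The largest values were -0.81 for miR-106b, -0.66 for miR-17-5p, -0.55 for 1 of 2 miR-20a probes and -0.45 for miR-19b. Adjusted over the list alone, 2 were lower. This list was not past the threshold without nematode wild type replicate 4 (adjusted p = 0.0835), with median scaling (0.0535) or among probes above blank spots (0.0644). The other lists had camera adjusted p values from 0.272 to 0.992. The let-7 (median -0.22), miR-30 (-0.20) and miR-15/16 (-0.06) families, the miR-29 family (0.08), miR-26 with miR-101 (-0.02), and the inflammatory (-0.00), miR-34 (0.06), erythroid (0.05), epithelial (-0.02), muscle and liver (0.00) and Dlk1-Dio3 (0.00) lists had 0 members past the threshold. miR-210 gave -0.25 (SE 0.19), and miR-126-3p and miR-126-5p 0.11 (SE 0.10) and 0.18 (SE 0.10). Fixed miRNAs that did not pass were miR-146 (-0.34, SE 0.11), miR-155 (-0.12, SE 0.23), miR-21 (-0.06, SE 0.18), miR-142-3p (-0.91, SE 0.46), miR-342 (-0.10, SE 0.15) and the star arm of miR-378 (0.22, SE 0.12).

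Groups did not overlap for 31 of 343 probes, where chance gives 2.86%. The calls of miR-422b, miR-125b, miR-223, miR-150 and miR-689 were kept in all 16 settings and without each of the 14 arrays in turn, and that of miR-720 ended with median scaling and with no normalization (adjusted p up to 0.229). The count rose from 6 to 12, 10 higher and 2 lower, without nematode wild type replicate 4, with miR-199b, miR-99a, miR-100, miR-365, miR-489 and miR-500 added, and to 14, 7 and 7, with cyclic loess.

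Within thioglycollate-elicited cells, 1 miRNA differed between genotypes. miR-34a was 2.24-fold lower in wild type than in IL-4R KO (log2 fold change -1.16, SE 0.13, limma adjusted p = 0.000340), at 6.39 ± 0.05 against 7.55 ± 0.21 (SD, n = 3 each). It stood above blank spots on 1 of 3 wild type and 3 of 3 IL-4R KO arrays. On slide 12, which holds 1 array of each genotype, the difference was -1.05. miR-422b gave 0.15 (95% confidence interval -0.40 to 0.70, adjusted p = 1), and -0.14 on slide 12. In the miR-34 and p53-linked list 1 of 6 fell, with a fry adjusted p of 0.0350 (0.0102 with fry's mixed test) and a camera adjusted p of 0.140.

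No list passed with camera in this comparison, where limma gave 14 of 343 probes an unadjusted p under 0.05 and chance gives 17.2. Groups did not overlap for 38 probes, where chance gives 10%. miR-125b gave 0.53 (SE 0.16, adjusted p = 0.287). The star arm of miR-378 (-0.10), miR-155 (0.26), miR-146 (0.23), miR-223 (0.33), miR-142-3p (-0.24), miR-199b (-0.16), miR-342 (0.29) and miR-150 (-0.11) did not pass either, and miR-21 was at 0 by normalization. Within slide 12, the values were 0.09 for miR-125b, -0.46 for the star arm of miR-378, 0.46 for miR-155, 0.24 for miR-146, -0.14 for miR-223, -0.48 for miR-142-3p, 0.22 for miR-342 and 0.03 for miR-150. The count was 5 without nematode IL-4R KO replicate 2 and 2 without nematode wild type replicate 4 or with the slide position as a factor.

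The interaction asked whether the genotype difference itself differed between elicitations, and 2 miRNAs passed. For miR-422b the wild type minus IL-4R KO difference was larger after nematode elicitation by 1.82 on the log2 scale (SE 0.34, limma adjusted p = 0.0224). For miR-34a the fitted value was 1.02 (SE 0.18, adjusted p = 0.0224). After nematode elicitation miR-34a stood above blank spots on 1 of 4 wild type and 0 of 4 IL-4R KO arrays, so its genotype difference there, and with it the size of the interaction, was not measured. miR-150 (-0.84, SE 0.19, adjusted p = 0.0935), miR-223 (1.01, SE 0.28, adjusted p = 0.211) and miR-125b (0.76, SE 0.21, adjusted p = 0.211) did not pass, so their genotype differences are not shown to differ between elicitations. miR-150 did pass with plain subtraction, median scaling, cyclic loess and no normalization and without nematode wild type replicate 2 or 4, and miR-125b with median scaling and no normalization. Values that did not pass in any setting or with any array left out were those of miR-146 (-0.57), miR-199b (0.96), miR-155 (-0.38), miR-342 (-0.39), miR-142-3p (-0.66), miR-21 (-0.06) and the star arm of miR-378 (0.32). With camera 0 lists passed, where limma gave 23 of 343 probes an unadjusted p under 0.05. The interaction count fell to 0 without thioglycollate wild type replicate 2 or 3 or thioglycollate IL-4R KO replicate 1 or 3, and to 1 without nematode wild type replicate 3 or nematode IL-4R KO replicate 2 or 3. It was 0 with no background correction, 1 with trend and robust, 4 with median scaling or none, and 7 without nematode wild type replicate 4.

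One miRNA, miR-422b, was called as higher both in wild type nematode against thioglycollate and in nematode wild type against IL-4R KO. In fits on only the groups compared the overlap was 0, since the former called 0 (limma, 23 at an unadjusted p under 0.05). These comparisons share the 4 nematode wild type arrays. Independent lists of the same size would share 0.0117 probes per direction, and 100 simulations of unchanged groups with the shared arrays gave a mean overlap of 0.01 and a highest of 1. The simulated groups held no changed probe, so an overlap near 0 was largely fixed in advance. A shift of the 4 shared arrays, which would enter both comparisons, was not simulated. With the shared arrays split by slide, miR-422b stayed past the threshold on both sides. Its log2 fold changes were 1.44 for elicitation and 2.38 for genotype with slide 9 in the former, and 2.25 and 1.56 with slide 7 in the former (adjusted p from 1.04e-05 to 0.00360). The study chose miR-378 and its star arm on these samples, so the list of both, with 1 of 2 members higher in each of these comparisons, is not independent evidence.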

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

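The tests of a single array, of normalization, of slides, of the position on the slide and of other cell types, and the division of the interaction splits by genotype grouping, were chosen after the results were seen; the counts over other splits of the samples were planned.

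Each named miRNA and several array measures were tested, in each nematode group of 4 arrays, for 1 array far from the rest. Of these 44 tests, 4 stood out, where chance, at about 1 in 20 tests, gives 2.2. The tests share arrays, so they are not independent and 2.2 is only a rough guide. In nematode wild type, replicate 4 correlated with the rest of its group at 0.867 against 0.95 to 0.956 for the others, a gap that fills 0.933 of the group's range. The same array had 41 spots with foreground below background against 4 to 9 (gap 0.865 of the range). In nematode IL-4R KO, miR-125b was at 6.47 in replicate 1 and at 6.68 to 6.70 in the others (gap 0.897 of the range). miR-720 was at 10.58 in nematode IL-4R KO replicate 3 and at 10.72, a tied rank of the quantile step, in the others (gap 1 of the range).

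Probes for the nematodes C. elegans and C. briggsae lie outside the comparisons of mouse miRNAs. In IL-4R KO, 3 of these 146 probes (cbr-miR-85, cel-miR-262 and cel-miR-264) were higher on nematode than on thioglycollate arrays after adjustment over the set (limma, smallest adjusted p = 0.0149), against 0 of 216 plant probes and 0 of 429 probes for other animals. At an unadjusted p under 0.05, 12 of the 146 nematode probes were higher and 4 lower, against 19 and 24 of 429 for other animals and 12 and 3 of 216 for plants; these shares were not tested against each other. Each of the 3 probes that passed stood above blank spots on at most 2 of the 4 nematode IL-4R KO arrays. On thioglycollate arrays, cel-miR-262 did so on 1 wild type array, cel-miR-264 on 1 IL-4R KO array and cbr-miR-85 on 0. In wild type 0 passed in limma, with 4 at an unadjusted p under 0.05.

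The genotype difference of miR-422b differed between elicitations by 1.82 (limma adjusted p = 0.0224), the miRNA being higher in nematode-elicited wild type cells than in the other groups, and this call ended without any 1 of thioglycollate wild type replicates 2 and 3, thioglycollate IL-4R KO replicates 1 and 3, nematode wild type replicate 3 and nematode IL-4R KO replicates 2 and 3 (adjusted p up to 0.0950, value 1.591 to 2.001). The same call ended with no background correction and with trend and robust. Over the settings its limma adjusted p reached 0.700, with values from 1.04 to 2.34. The test of a single array covered miR-422b in wild type elicitation and in the nematode genotype contrast, not the interaction, which single arrays did end. Against a single array as the cause of those pairwise differences, the lowest log2 fold change with each array left out was 1.62, past the threshold each time. These fits share the spread of all groups. In the fit on only the groups compared, wild type elicitation gave miR-422b a limma adjusted p of 0.133. Against quantile normalization, the nematode genotype difference was 1.75 with no normalization. A slide effect stays open and cannot be told apart from the groups: the 2 slides of nematode wild type differed by 0.82, and every nematode slide holds 1 group and was scanned beside the other slide of that group. A difference that needs the IL-4 receptor is the explanation the design names, and it stays a hypothesis.

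miR-150 was lower, and miR-125b and miR-223 were higher, in nematode-elicited wild type than IL-4R KO cells, from a preparation selected by adherence and more than 80% pure. Members of the lists below were counted where they stood above blank spots on at least 3 nematode arrays. Lymphocytes among the IL-4R KO cells could bring miR-150, but only 2 other members of that list were counted, miR-342 and miR-326. Their median was -0.12 against -0.96 for miR-150. Stromal cells among the wild type cells could bring miR-125b, and the 2 members counted, miR-199b (0.80) and miR-10a (0.36), had a median of 0.58. miR-199b stood above blank spots on only 3 nematode arrays, with a low IL-4R KO mean of 6.03, so its value is uncertain. Granulocytes could bring miR-223, which the myeloid list also holds, yet 0 of the other 4 members of the granulocyte list were counted (median 0.00). With so few measurable members, these sources cannot be told apart from a change within macrophages between the genotypes, which was not tested.

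The genotype difference of miR-34a also differed between elicitations, by a fitted 1.02 (limma adjusted p = 0.0224), a call that ended without any 1 of thioglycollate wild type replicates 2 and 3 and thioglycollate IL-4R KO replicates 1 and 3 (adjusted p up to 0.0746, fitted value 0.90 to 1.105). Since miR-34a stood above blank spots on 1 of 4 nematode wild type and 0 of 4 nematode IL-4R KO arrays, neither the size of 1.02 nor the absence of a genotype difference after nematode elicitation can be read from it. The position on the slide is argued against as the whole cause, since the thioglycollate difference was -1.16 with position as a factor. A slide effect stays open: on slide 12 the difference was -1.05, but that is 1 pair of arrays. A difference from the genotype itself stays open too, as untested.

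For the nematode against thioglycollate comparison in wild type, 3 of 35 splits of the same 7 arrays gave as many calls as the real 3 (highest other 5), so chance cannot be excluded for that count. The split with 5 calls set the thioglycollate arrays and nematode wild type replicate 4 against the other nematode arrays, so it carried much of the elicitation difference. The split with 4 calls mixed both elicitations on each side. For the same contrast in IL-4R KO, 1 of 35 splits, the real one, gave 5 calls (highest other 0). In the nematode genotype contrast, 1 of 35 gave 6 (highest other 1). These shares lie under 0.05, but they are the smallest that 35 splits can give and were not corrected over the contrasts. The splits also take single arrays as exchangeable, while every nematode slide holds 1 group and replicates may be technical. Chance between slides or animals is therefore not excluded for these counts. The thioglycollate genotype contrast has only 10 splits, too few for a share under 0.05, with 1 call in the real split and a highest other of 0. For the interaction, 6 of 100 splits gave at least the real 2 (highest other 11), so chance cannot be excluded by this count. The 5 other splits among these each kept the real genotype groups of 1 elicitation and so carried its genotype difference, which makes the count a weak test. Of the 83 splits that mixed genotypes in both elicitations 0 reached 2 calls (highest 1). Mixing also adds the real group differences to the spread of the same probes, which makes calls less likely there. That 0 therefore does not exclude chance. For miRNA lists past the threshold, chance cannot be excluded in wild type elicitation (2 of 35 splits gave 2 lists, highest other 2) or in the nematode genotype contrast (4 of 35 gave at least 1, highest other 2).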

How the results depend on the processing

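The filter on blank spots, the offset of 20 the list tests without nematode wild type replicate 4 and the overlap in fits on only the groups compared were chosen after the data were seen; all other alternatives were planned. Over the settings, no called value changed sign. Calls of miR-422b, miR-125b, miR-223, miR-150 and miR-689 in the nematode genotype contrast, of miR-34a, miR-150 and miR-222 in IL-4R KO elicitation, and of miR-34a in the thioglycollate genotype contrast held in every setting and without each array. The miR-34a calls share the thioglycollate IL-4R KO arrays. Calls of miR-150 and miR-689 in IL-4R KO elicitation and in the nematode genotype contrast share the nematode IL-4R KO arrays. Calls that share arrays are not independent findings. Named values past the threshold fell below it in 25 cases over the settings and 35 with an array left out, and values short of it passed in 30 and 8. The planned filters removed no probe, so they test nothing, and the spot mean in place of the spot median was not run, since the files used here give 1 foreground value per spot. Low signal over background is a limit: 208 of 343 mouse probes stood above blank spots on 3 arrays.

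For nematode vs thioglycollate in wild type (3 calls) the count was 5 with no background correction, 1 with plain subtraction, cyclic loess or no normalization, 9 with the median of spots, 0 in the fit on only the groups compared (23 at an unadjusted p under 0.05 in limma; fewer samples), 8 above blank spots (fewer probes) and 2 to 9 without 1 array. For nematode vs thioglycollate in IL-4R KO (5 calls) it was 10 with cyclic loess, 8 with no normalization, 11 on only the groups compared and 3 to 8 without 1 array. For wild type vs IL-4R KO in nematode-elicited (6 calls) it was 14 with cyclic loess, 10 with trend and robust, above blank spots or with an offset of 20, and 6 to 12 without 1 array. For wild type vs IL-4R KO in thioglycollate-elicited (1 call) it was 2 with position as a factor and 1 to 5 without 1 array. For the interaction of elicitation and genotype (2 calls) it was 0 with no background correction (17 at an unadjusted p under 0.05), 4 with median scaling or no normalization, 1 with trend and robust and 0 to 7 without 1 array. The overlap of the wild type elicitation calls and the nematode genotype calls was 2 with median scaling, 0 in the fits on only the groups compared, where wild type elicitation had 0 calls, and 1 to 5 without 1 array. The correlation of the elicitation effect between genotypes (0.295) was 0.347 with median scaling or no normalization, 0.26 with the median of spots and 0.222 to 0.325 without 1 array. Where no construction shows it, the cause was not tested.

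Higher and lower calls, main 1 and 2, 3 and 2, 4 and 2, were 2 and 2, 3 and 3, 3 and 3 with median scaling, 1 and 0, 6 and 4, 7 and 7 with cyclic loess, and 1 and 0, 4 and 4, 4 and 3 with no normalization. In the interaction, 2 and 0 became 3 and 1 with median scaling or none and 2 and 1 with loess. Against the reported fit, no normalization moved the median of all probes by 0.12 (wild type elicitation), 0.14 (interaction) and -0.085 (thioglycollate genotype contrast), to be taken off changes there. miR-150, interaction of elicitation and genotype, passed with plain subtraction, median scaling, cyclic loess and no normalization (adjusted p 0.00407 to 0.0497), and miR-125b, interaction of elicitation and genotype, with median scaling (0.00954) and no normalization (0.0263).

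Of the miRNA list tests, nematode vs thioglycollate in wild type (2 lists) gave 1 above blank spots, 1 without nematode wild type replicate 4 and 0 with estimated correlation. Nematode vs thioglycollate in IL-4R KO (0 lists) gave 1 with median scaling. Wild type vs IL-4R KO in nematode-elicited (1 list) gave 0 with median scaling, above blank spots, without nematode wild type replicate 4 and with estimated correlation. Wild type vs IL-4R KO in thioglycollate-elicited (0 lists) gave 1 with median scaling and 1 above blank spots, and the interaction (0 lists) gave 1 above blank spots. With slide as a random block (consensus correlation -0.019) the counts of lists did not change, and the only change among calls was miR-18, added in wild type elicitation. The authors' value table plus 50 gave the calls reported.

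Only values short of the threshold changed sign. The log2 fold change of miR-142-3p, nematode vs thioglycollate in IL-4R KO (0.01), was -0.479 with median scaling, -0.34 with loess, -0.497 with no normalization and -0.111 with the median of spots. That of miR-92, nematode vs thioglycollate in wild type, was 0.027 with the median of spots. miR-342, wild type vs IL-4R KO in nematode-elicited, was 0.029 with no background correction, and miR-155, wild type vs IL-4R KO in nematode-elicited, 0.004 with loess. In wild type vs IL-4R KO in thioglycollate-elicited, miR-422b was -0.047 with median scaling and -0.138 with no normalization, miR-223 -0.151 and -0.242, miR-146 -0.023 and miR-342 -0.009 with no normalization (0.06 and 0.08 once the move of the median is taken off, so these signs come from it), and the array's miR-378 0.011 with the median of spots. miR-21, interaction of elicitation and genotype, was 0.01 with position. Without 1 array, ranges crossed 0 for miR-155, nematode vs thioglycollate in wild type (-0.093 to 0.372) and miR-92, nematode vs thioglycollate in wild type (-1.402 to 0.194). They did for miR-422b, nematode vs thioglycollate in IL-4R KO (-0.114 to 0.16), the star arm of miR-378, nematode vs thioglycollate in IL-4R KO (-0.199 to 0.049) and miR-142-3p, nematode vs thioglycollate in IL-4R KO (-0.296 to 0.268). Genotype ranges that crossed 0 were those of miR-155, wild type vs IL-4R KO in nematode-elicited (-0.326 to 0.139), miR-21, wild type vs IL-4R KO in nematode-elicited (-0.203 to 0.128), the star arm of miR-378, wild type vs IL-4R KO in thioglycollate-elicited (-0.192 to 0.056) and miR-142-3p, wild type vs IL-4R KO in thioglycollate-elicited (-0.396 to 0.003). The last was miR-21, interaction of elicitation and genotype (-0.203 to 0.128).

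The replicate numbers share only a number. Deviations of same-numbered arrays correlated at a median of -0.007 over 19 pairs, 5 of them over 0.1, and 2 of 14 arrays lay closest to their own number. With the replicate block the counts were 3, 4, 9 and 2 for the comparisons in the order above and 2 for the interaction, and 1 list passed in nematode vs thioglycollate in IL-4R KO. The miR-17-92 list ended there in wild type elicitation (adjusted p = 0.0767), and miR-422b, nematode vs thioglycollate in IL-4R KO, was -0.106.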

Other observations

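The miRNA and the correlations in this part were chosen after the results were seen.

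The star arm of miR-140 had like values in both elicitation contrasts, short of the threshold in each. miR-140* gave -0.53 in wild type and -0.51 in IL-4R KO (limma adjusted p = 0.0649 and 0.0715), and stood above blank spots on 13 of 14 arrays. Its interaction was -0.02 (adjusted p = 0.984). It passed in wild type with the median of spots and among probes above blank spots, in both contrasts without nematode IL-4R KO replicate 1, and in IL-4R KO without nematode wild type replicate 4.

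Deviations from group means were also set against the position on the slide. Over pairs of arrays of different groups at the same position these deviations correlated at a median of 0.12, with 21 of 36 pairs over 0.1. At different positions the median was -0.121, with 0 of 37 over 0.1, which is not separate evidence, since deviations sum to 0 within a group. With position as a factor, miR-551b was no longer called in IL-4R KO elicitation and miR-710 was called in the thioglycollate genotype contrast, and no other call changed.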
